A study of Arabidopsis thaliana with 27 samples.

How the data were processed

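Rosette leaves of 3-week-old Arabidopsis plants (Col-0) of WT, caf1a and caf1b were taken at 0, 30 and 90 min after wounding. Each of the 9 combinations had 3 biological replicates, and each replicate was hybridised to 1 of 27 2-colour arrays. Per the labels, RNA was isolated with TRIzol and a column with DNase treatment, copied to cDNA with oligo(dT) primers and amplified to labelled cRNA. The labels give Cy3 for the sample and Cy5 for a pool of all samples.

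Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 9.5.3.1, and the mean spot signal and the median local background of each channel are deposited as intensity. Per the file headers, the scanner's processed signals are also an intensity, and its ratio column is the log10 of Cy5 over Cy3. The value table deposited by the authors is in log10 of Cy3 over Cy5: on every array it equalled the scanner's ratio with the sign turned, within 0.005, and 15.8% to 28.9% of its entries were exactly 0. The flags of Feature Extraction and the control type of each spot, of unit other, are deposited too and were used to filter spots. No column of values was left unused. Probe coordinates are given without a build in the sources used here, and the gene table supplied gave names and descriptions only.

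Which dye carried the sample was tested on the values, because the sign of each result depends on it. Over 19574 spots bright in both channels, the median variance across arrays was 0.0110 in Cy3 and 0.0827 in Cy5, and the mean correlation between arrays was 0.994 in Cy3 and 0.953 in Cy5. The Cy5 signal of CAF1a ranged from 178 to 541 on the caf1a arrays and from 1942 to 43019 on the others, and its Cy3 signal stayed between 6713 and 11753 on the others. The values show Cy5 as the sample and Cy3 as the pool, the reverse of the labels, on all 27 arrays. All ratios are therefore log2 of Cy5 over Cy3; with the dyes as labelled every sign turns. Between arrays the lowest correlation of ratios was -0.49, between samples of different times, and 53 of 351 pairs lay under -0.3.

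Signals were corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1, with statmod 1.5.0 and data.table (version 1.17.8) under R 4.3.3. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Control spots and outlier values were left out, and features were kept when well above background in Cy3 on at least 3 arrays, a filter fixed before the dye test. Of 37685 non-control spots, covering 37478 probes and 25665 loci, 25682 features were tested: 21432 loci and 4250 probes without a locus, with 777 missing values. For the 541 loci with more than 1 probe the brightest probe was used; 234 probes matched more than 1 locus.

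Spots well above background in Cy3 numbered 20996 to 25499 per array (55.7% to 67.7%), and 22136 to 28571 in Cy5. At most 2 spots were saturated on an array, and outlier spots numbered 14 to 237. The median coefficient of variation between repeated spots on an array was between 11.8% and 19.6% in Cy3. Correlations between replicates of a group ranged from 0.435 to 0.924. Arrays were also simulated with independent normal noise of each feature's residual spread. They held no trend shared by features and no slide effect, so the shares do not cover these. After changes were added, the comparison of WT at 30 and 0 min recovered 44.8% of 1.41-fold, 92.5% of 2-fold and 100% of 4-fold changes. There were 4 false calls among 25482 features. For the caf1b difference in the 30 min wound response the shares were 11.9%, 74.6% and 100%, with 3 false calls.

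One linear model with the 9 groups was fitted in limma with moderated variances (prior 5.54 and residual 18 degrees of freedom), and adjusted p values are Benjamini-Hochberg values over all features of a comparison, called at 0.05. Before the data were examined, 17 comparisons were fixed: each wounded time against 0 min within each genotype, each mutant against WT at each time, each mutant's difference from WT in the wound response, and caf1b against caf1a averaged over the 3 times. Those of WT at 90 against 30 min and of each mutant against WT averaged over the 3 times were added after the data were seen. Gene lists, 24 with 400 entries chosen from general knowledge before the data were examined, were tested with camera (preset correlation 0.01) and again with an estimated correlation; 3 entries were dropped and 391 genes were measured. The lists cover jasmonate biosynthesis, JAZ repressors, jasmonate catabolism, jasmonate response markers, rapid stress transcription factors, calcium sensors and touch genes, mRNA decay, salicylic acid and pathogen response, oxidative stress, indole glucosinolates and camalexin, aliphatic glucosinolates, abscisic acid with drought and cold, heat shock and chaperones, photosynthesis, the circadian clock, auxin, ethylene, senescence, the cell cycle, guard cells, phloem and xylem, epidermis, floral genes and reference genes. Counts adjusted over the list alone used the p values of the list's genes only. Genes named for their values were chosen from the largest changes that passed and had a symbol in the reference file, and in comparisons of 2 groups or of means over time only where the arrays of the 2 groups did not overlap (at each time for means), so larger changes without these properties are not named; SEs are those of the model.

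The 27 arrays lay on 7 slides of up to 4 arrays, each scanned once, and slide was largely confounded with genotype and time. Slide was therefore tried as a random block (consensus correlation -0.02) and as a fixed block where that could be estimated, which was the case for 6 comparisons, and within a slide holding both groups. Further alternatives were the scanner's processed signals, the deposited value table, quantile normalisation between arrays, and no filter on dim features. Others were a filter of at least 14 arrays, the mean over probes of a gene, replicate number as a block, only the groups of the comparison, and leaving out each array in turn. Quantile normalisation of the average brightness leaves ratios as they are, so that alternative gave the same values by construction. Added after the data were seen were a filter on Cy5, the removal of 3 caf1a arrays that stood apart on principal component 3, and a covariate of each array. That covariate is the median log2 ratio of 342 genes of families known for long products minus that of 444 genes of families known for short products, chosen by words in their descriptions; transcript lengths were not in the reference. Random regroupings moved arrays between the compared groups and repeated each test, 10 splits for comparisons of 2 groups and 100 random ones for the others.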

Results

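Rosette leaves of wild type (WT) Arabidopsis and of 2 mutants, caf1a and caf1b, were compared at 0, 30 and 90 min after wounding, with 3 arrays per genotype and time. The samples at 0 min were unwounded, and no unwounded samples are listed at 30 or 90 min. Changes from 0 min, called wound responses below, therefore hold wounding and elapsed time together. CAF1a and CAF1b are deadenylases of the CCR4-NOT complex, which shortens mRNA poly(A) tails. All signed values are log2 of the sample over the pooled reference with the dyes as the values show them, Cy5 for the sample; with the dyes as labelled every sign turns and every rise reads as a fall. Transcript levels of the 2 disrupted genes followed the genotypes. CAF1a stood at -2.02 ± 0.21 (SD, n = 3) in unwounded WT, 1.77 ± 0.32 at 30 min and -0.58 ± 0.65 at 90 min. In caf1a its values were -5.03 ± 0.28, -4.22 ± 0.10 and -4.0 ± 0.63 at these times. CAF1b stood at -2.95 ± 0.28, 1.36 ± 0.73 and -0.44 ± 0.32 in WT, and at -3.56 ± 0.25, -3.21 ± 0.09 and -3.05 ± 0.19 in caf1b. At 0 min the CAF1b value of caf1b differed from WT by -0.61, which did not pass the test (adjusted p = 0.656). The position of the insertions relative to the probes is not given in the sources used here.

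**Figure D1:**
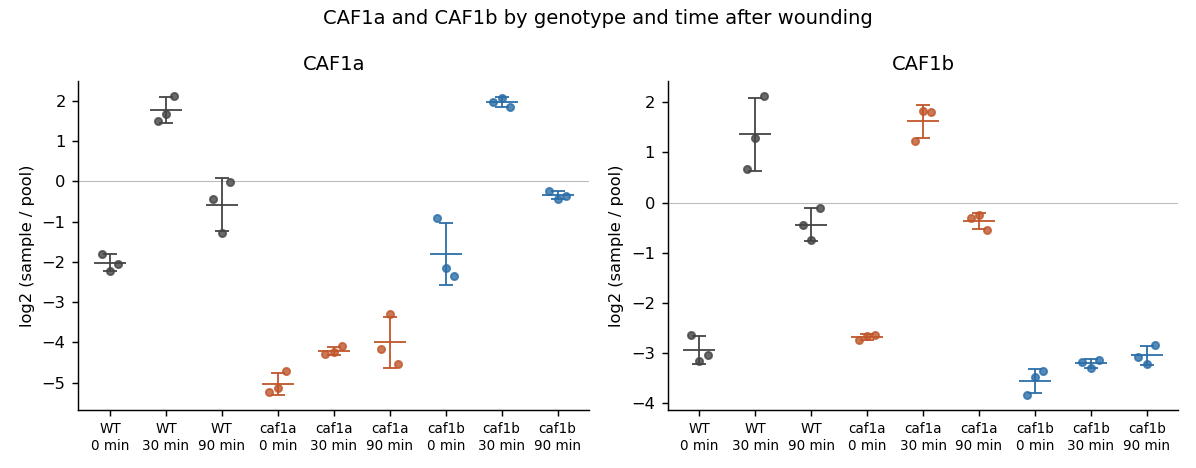
Log2 ratio of sample over pooled reference (vertical axis) for CAF1a (left) and CAF1b (right) on each of the 27 arrays, by genotype and time (horizontal axis); points are arrays, the bar is the mean and the whiskers are the SD of 3 arrays. CAF1a reached a mean of 1.77 in WT at 30 min and -4.22 in caf1a at that time.

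In WT at 30 min after wounding, genes of calcium sensing, of fast stress transcription and of jasmonate signalling rose most. The largest rises of genes with a symbol in the reference annotation, on the log2 scale with the SE of the fit, were 6.43 ± 0.24 for the calmodulin-like protein CML38 (86.2-fold), 6.34 ± 0.18 for the AP2-type transcription factor DDF1 and 6.25 ± 0.19 for SRO5. Next were 6.16 ± 0.22 for the transcription factor WRKY40 and 5.98 ± 0.22 for RRTF1, a redox-responsive transcription factor. They were followed by 5.89 ± 0.34 for CYP94C1, an enzyme that oxidises jasmonoyl-isoleucine, 5.76 ± 0.18 for the jasmonate repressor JAZ7, 5.57 ± 0.32 for ERF13, 5.51 ± 0.21 for the F-box protein FBS1 and 5.33 ± 0.19 for MYB15. Large falls included -2.12 ± 0.19 for the protein kinase CIPK5, -1.98 ± 0.22 for COL2, -1.82 ± 0.14 for BBX15, -1.82 ± 0.23 for MYB48 and -1.77 ± 0.26 for the expansin EXPA8. For these 15 genes the largest adjusted p was 1.43e-05 (limma, n = 3 arrays per group). Here and in later comparisons, the largest changes are those among genes with a symbol whose arrays did not overlap between the groups. In all, 3027 features were higher and 1726 lower of 25682 tested, 1247 and 193 of them by at least 2-fold. With the scanner's processed signals the 2 directions were 2506 and 2927, so the balance of rises and falls depends on the scaling.

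The gene lists fixed before the data were examined moved as follows in WT at 30 min. All 36 rapid stress transcription factors rose (36 and 0 adjusted over the list alone), among them WRKY18 at 5.18 ± 0.25. The median was 2.96 (camera adjusted p = 5.73e-49; adjusted p = 0.00212 with an estimated correlation). Among 19 calcium sensors and touch genes 17 rose and 0 fell (17 and 0 adjusted over the list alone), with 5.86 for CML40, 5.33 for CML37 and 4.29 for TCH4. The median was 2.12 (camera adjusted p = 9.10e-20; adjusted p = 0.00717 with an estimated correlation). Of the 12 JAZ repressors 10 rose and 0 fell (10 and 0 adjusted over the list alone), with 4.53 for JAZ8 and 3.74 for JAZ1. The median was 2.16 (camera adjusted p = 1.84e-14; adjusted p = 0.00717 with an estimated correlation). Ethylene genes numbered 16, of which 9 rose and 0 fell (9 and 0 adjusted over the list alone), with ERF1 at 3.25. The median was 0.53 (camera adjusted p = 0.000133; adjusted p = 0.0113 with an estimated correlation). In jasmonate biosynthesis, of 14 genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), with 4.78 for LOX4, 4.43 for LOX3 and 3.65 for OPR3. The median was 1.49 (camera adjusted p = 3.68e-06; adjusted p = 0.113 with an estimated correlation). Jasmonate catabolism held 9 genes, of which 8 rose and 0 fell (8 and 0 adjusted over the list alone), with 3.51 for CYP94B1 and 5.89 for CYP94C1. The median was 2.31 (camera adjusted p = 2.26e-07; adjusted p = 0.113 with an estimated correlation). The mRNA decay list held 27 genes, of which 6 rose and 0 fell (6 and 0 adjusted over the list alone), including 4.31 ± 0.24 for CAF1b, 3.79 ± 0.32 for CAF1a, 3.06 ± 0.36 for AT1G61470 and 2.59 ± 0.33 for AT1G27890, all of the CAF1 family. The median was 0.04 (camera adjusted p = 0.0532; adjusted p = 0.264 with an estimated correlation).

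For 7 other lists camera made a call in WT at 30 min that did not hold with an estimated correlation. Auxin response genes numbered 20, of which 4 rose and 11 fell (5 and 11 adjusted over the list alone), with -1.95 for SAUR16, -1.59 for SAUR20 and -1.47 for SAUR15. The median was -0.84 (camera adjusted p = 0.000321; adjusted p = 0.279 with an estimated correlation). Aliphatic glucosinolate synthesis held 11 genes, of which 0 rose and 4 fell (0 and 4 adjusted over the list alone), with -1.08 for MYB28 and -0.62 for CYP83A1, MYB28 being a regulator of the pathway. The median was -0.32 (camera adjusted p = 0.00767; adjusted p = 0.382 with an estimated correlation). Heat shock and chaperone genes numbered 21, of which 6 rose and 0 fell (6 and 0 adjusted over the list alone), with 2.96 for DREB2A and 1.58 for HSFA2. The median was 0.40 (camera adjusted p = 0.00238; adjusted p = 0.377 with an estimated correlation). For abscisic acid, drought and cold, of 24 genes 10 rose and 2 fell (11 and 4 adjusted over the list alone), with 3.02 for the abscisic acid synthesis gene NCED3. The median was 0.43 (camera adjusted p = 0.0211; adjusted p = 0.448 with an estimated correlation). Oxidative stress genes numbered 24, of which 8 rose and 2 fell (8 and 2 adjusted over the list alone), with 4.25 for BAP1, 1.64 for RBOHD and -1.41 for VTC2. The median was 0.34 (camera adjusted p = 0.01; adjusted p = 0.213 with an estimated correlation). Photosynthesis had 31 genes, of which 0 rose and 3 fell (0 and 2 adjusted over the list alone), with -0.74 for ELIP1 and -0.58 for RBCS1A. The median was -0.12 (camera adjusted p = 0.0488; adjusted p = 0.448 with an estimated correlation). Guard cell markers numbered 7, of which 0 rose and 2 fell (0 and 2 adjusted over the list alone), MYB60 at -0.62 and OZS1 at -0.58. The median was -0.35 (camera adjusted p = 0.0139; adjusted p = 0.113 with an estimated correlation).

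For the remaining lists at 30 min in WT camera made no call. Salicylic acid and pathogen response had 19 genes (6 rose and 0 fell, 7 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 0.0624), with GRX480 at 4.72. Senescence and dark-induced genes numbered 11 (5 rose and 2 fell, 5 and 2 adjusted over the list alone; 0.75, 0.0532), with SAG21 at 2.48 and ASN1 at 1.96. Jasmonate response markers also numbered 11 (2 rose and 0 fell, 2 and 0 adjusted over the list alone; 0.07, 0.0604), with MYC2 at 2.71. Indole glucosinolate and camalexin synthesis had 11 genes (3 rose and 0 fell, 4 and 0 adjusted over the list alone; 0.47, 0.183), with SOT16 at 1.18. The 20 clock genes went both ways (7 rose and 7 fell, 7 and 8 adjusted over the list alone; 0.08, 0.772), with PRR5 at 1.37. No cell cycle, phloem and xylem, floral or reference gene passed the test, the medians being 0.19, 0.03, 0.18 and 0.07 over 9, 14, 10 and 9 genes, with camera adjusted p of 0.278, 0.812, 0.62 and 0.874. The 6 epidermis markers gave 1 rise and 1 fall (median -0.09, 0.52). With the scanner's processed signals the medians of the clock, mRNA decay, phloem and xylem, and reference lists turned to -0.07, -0.04, -0.06 and -0.04. Within slide 5, which held 3 unwounded arrays and 1 array at 30 min, 3358 features changed, and the fit with slide as a block gave 3353. The rapid transcription factors then had a median of 2.99, and the JAZ repressors 2.66. Calls were lost for photosynthesis (0.01, adjusted p = 0.283), aliphatic glucosinolates (-0.20, 0.15) and guard cell markers (-0.20, 0.0779), and 1 was gained for jasmonate response markers (0.81, 0.000338).

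In WT at 90 min the jasmonate pathway led. Rises were 6.48 ± 0.37 for CYP94B3 (89-fold), 5.87 ± 0.68 for CYP94B1 and 5.83 ± 0.34 for CYP94C1, the 3 enzymes that oxidise jasmonoyl-isoleucine, and 5.34 ± 0.41 for the lipoxygenase LOX3. Among the largest were also 5.45 ± 0.47 for UGT76E12, 5.43 ± 0.27 for the gibberellin-inactivating enzyme GA2OX6, 5.43 ± 0.68 for RAP2.6, 5.36 ± 0.41 for CYP82G1, 5.26 ± 0.31 for ERD7 and 5.21 ± 0.21 for FBS1. The largest falls were -2.79 ± 0.22 for COL2, -2.72 ± 0.26 and -2.34 ± 0.18 for the expansins EXPA8 and EXPB1, -2.36 ± 0.33 for ESE3 and -2.22 ± 0.23 for the cell wall enzyme XTH31. Among these 15 genes the largest adjusted p was 3.45e-06 (limma, n = 3 arrays per group). In all, 4560 features were higher and 3474 lower, 1650 and 477 by at least 2-fold; with the processed signals these were 3736 and 4949. With slide as a block 3947 changed, and CAF1a no longer passed.

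Lists whose camera calls held with an estimated correlation in WT at 90 min covered jasmonate, stress and ethylene. Jasmonate biosynthesis (12 rose and 0 fell of 14; 12 and 0 adjusted over the list alone) included 4.40 for JAR1, 4.26 for OPR3 and 3.93 for LOX4. The median was 2.63 (camera adjusted p = 1.47e-08; adjusted p = 0.033 with an estimated correlation). All 9 catabolism genes rose, adjusted over the list alone too (median 3.98, camera adjusted p = 2.46e-11, and adjusted p = 0.033 with an estimated correlation). JAZ repressors (10 rose and 0 fell; 10 and 0 adjusted over the list alone) included JAZ10 at 4.79 ± 0.45. The median was 2.48 (camera adjusted p = 8.66e-12; adjusted p = 0.0296 with an estimated correlation). Rapid stress transcription factors (31 rose and 0 fell; 31 and 0 adjusted over the list alone) included NAC019 at 5.02 ± 0.44. The median was 2.31 (camera adjusted p = 1.71e-23; adjusted p = 0.0296 with an estimated correlation). Abscisic acid, drought and cold genes (19 rose and 0 fell; 20 and 0 adjusted over the list alone) included 4.51 for LTI78, 4.25 for LTI30 and 3.91 for HAI1. The median was 1.97 (camera adjusted p = 2.40e-12; adjusted p = 0.0296 with an estimated correlation). Heat shock and chaperone genes (18 rose and 0 fell; 19 and 0 adjusted over the list alone) included 3.85 for HSP17.8 and 3.85 for HSFA2. The median was 1.88 (camera adjusted p = 2.12e-11; adjusted p = 0.033 with an estimated correlation). Calcium and touch genes (13 rose and 0 fell; 14 and 0 adjusted over the list alone) gave median 1.39, camera adjusted p = 2.50e-09, and adjusted p = 0.0462 with an estimated correlation. Oxidative stress genes (15 rose and 3 fell; 16 and 3 adjusted over the list alone) included 3.93 for GSTU4 and 2.67 for GSTU1, both glutathione transferases. The median was 0.63 (camera adjusted p = 0.000143; adjusted p = 0.0449 with an estimated correlation). Ethylene genes (9 rose and 0 fell; 9 and 0 adjusted over the list alone) gave median 0.70, camera adjusted p = 0.000501, and adjusted p = 0.0296 with an estimated correlation.

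Further lists changed in WT at 90 min without holding under the estimated correlation. Jasmonate response markers (8 rose and 0 fell; 8 and 0 adjusted over the list alone) included TAT3 at 2.92. The median was 1.55 (camera adjusted p = 7.39e-06; adjusted p = 0.0795 with an estimated correlation). Indole glucosinolate and camalexin synthesis (8 rose and 0 fell; 8 and 1 adjusted over the list alone) included 2.68 for CYP71A13 and 2.25 for PAD3, both of camalexin synthesis. The median was 1.11 (camera adjusted p = 0.00439; adjusted p = 0.235 with an estimated correlation). Aliphatic glucosinolate synthesis (0 rose and 7 fell; 0 and 7 adjusted over the list alone) included -1.32 for MYB28, -1.18 for CYP83A1 and -1.03 for SOT18. The median was -0.59 (camera adjusted p = 2.27e-05; adjusted p = 0.115 with an estimated correlation). Photosynthesis (0 rose and 11 fell; 0 and 11 adjusted over the list alone) included -1.28 for ELIP2, -0.84 for RBCS1B and -0.80 for PRK. The median was -0.27 (camera adjusted p = 0.00121; adjusted p = 0.176 with an estimated correlation). Auxin response (5 rose and 11 fell; 6 and 11 adjusted over the list alone) included -2.20 for SAUR22 and -2.07 for SAUR15. The median was -0.88 (camera adjusted p = 0.000866; adjusted p = 0.235 with an estimated correlation). Senescence genes (7 rose and 0 fell; 7 and 0 adjusted over the list alone) included ASN1 at 3.54. The median was 0.65 (camera adjusted p = 0.000341; adjusted p = 0.0795 with an estimated correlation). Clock genes (11 rose and 5 fell, 12 and 6 adjusted over the list alone) gave median 0.45, with 4.31 for PRR5 and -2.17 for LHY. The camera adjusted p was 0.0261, and adjusted p = 0.171 with an estimated correlation. For clock genes above all, elapsed time cannot be told apart from wounding.

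No camera call was made at 90 min in WT for the lists that follow. Salicylic acid genes (6 rose and 1 fell, 6 and 1 adjusted over the list alone) had a median of 0.36 (camera adjusted p = 0.106), with GRX480 at 3.42. The mRNA decay list (5 rose and 0 fell, 5 and 0 adjusted over the list alone) had a median of 0.16 (0.291), which was -0.02 with the scanner's processed signals, and CAF1b rose by 2.51 ± 0.24 and CAF1a by 1.45 ± 0.32. Cell cycle, guard cell, phloem and xylem, epidermis, floral and reference lists had medians of 0.04, -0.15, -0.03, 0.09, 0.17 and 0.18, with camera adjusted p of 0.931, 0.455, 0.681, 0.774, 0.834 and 0.495. The cell cycle median was -0.09 with the processed signals. Of the reference genes, PEX4 rose by 0.52 ± 0.12 and MON1 by 0.33 ± 0.10. With slide as a block the auxin and photosynthesis medians were -0.48 and -0.15, both calls lost (adjusted p = 0.0775 and 0.0775), and that of the clock genes was 0.43, its call lost too (0.0762).

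In caf1a at 30 min the largest rises were 6.31 ± 0.24 for CML38, 6.24 ± 0.21 for DDF1, 5.90 ± 0.22 for RRTF1, 5.75 ± 0.19 for SRO5 and 5.59 ± 0.34 for CYP94C1. Large falls included -2.03 ± 0.22 for COL2, -1.99 ± 0.19 for CIPK5, -1.71 ± 0.23 for MYB48, -1.62 ± 0.21 for CDF3 and -1.50 ± 0.18 for VTC2, VTC2 being an enzyme of ascorbate synthesis. In all, 3253 features were higher and 1980 lower, 1177 and 144 by at least 2-fold (2957 and 3183 with the processed signals). Rapid stress transcription factors (35 rose and 0 fell of 36; 36 and 0 adjusted over the list alone) gave median 2.78, camera adjusted p = 4.71e-46, and adjusted p = 0.00296 with an estimated correlation. JAZ repressors (10 rose and 0 fell of 12; 10 and 0 adjusted over the list alone) gave median 2.05, camera adjusted p = 1.79e-12, and adjusted p = 0.013 with an estimated correlation. Jasmonate biosynthesis (9 rose and 0 fell of 14; 9 and 0 adjusted over the list alone) gave median 1.21, camera adjusted p = 0.00026, and adjusted p = 0.231 with an estimated correlation. CAF1b rose by 4.29 ± 0.24, while CAF1a in its own mutant gave 0.81 ± 0.32, which did not pass (adjusted p = 0.0734). Residuals of arrays with the same replicate number correlated here, between 0.165 and 0.548. The sample titles do not say that these numbers pair samples. At 90 against 0 min the same correlations lay between -0.306 and 0.124. Replicate 3 lay far along principal component 3 at both 0 and 30 min (39.04 and 44.39). The fit with replicate number as a block gave 4928 features. Fitted from these 6 arrays alone, 2650 changed.

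In caf1a at 90 min the largest rises were 5.89 ± 0.34 for CYP94C1, 5.74 ± 0.37 for CYP94B3, 5.39 ± 0.68 for CYP94B1, 5.14 ± 0.31 for ERD7 and 5.06 ± 0.41 for LOX3. The largest falls were -2.80 ± 0.22 for COL2, -2.64 ± 0.29 for ANK, -2.49 ± 0.43 for LURP1, -2.25 ± 0.26 for EXPA8 and -2.17 ± 0.23 for XTH31. In all, 4396 features were higher and 2300 lower, 1541 and 299 by at least 2-fold (4160 and 4467 with the processed signals). All 9 jasmonate catabolism genes rose, adjusted over the list alone too (median 3.73, camera adjusted p = 5.44e-11, and adjusted p = 0.0391 with an estimated correlation). Heat shock genes (17 rose and 0 fell of 21; 18 and 0 adjusted over the list alone) gave median 1.12, camera adjusted p = 7.26e-10, and adjusted p = 0.0391 with an estimated correlation. Photosynthesis (0 rose and 17 fell of 31; 0 and 19 adjusted over the list alone) gave median -0.43, camera adjusted p = 6.35e-08, and adjusted p = 0.0391 with an estimated correlation. CAF1a gave 1.02 ± 0.32 in its own mutant (adjusted p = 0.0174), and without replicate 2 at 90 min it gave 0.68 and did not pass.

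In caf1b at 30 min the largest rises were 6.70 ± 0.18 for DDF1, 6.38 ± 0.34 for CYP94C1, 6.34 ± 0.22 for WRKY40, 6.31 ± 0.24 for CML38 and 6.29 ± 0.22 for RRTF1. Large falls included -2.27 ± 0.19 for CIPK5, -1.88 ± 0.23 for MYB48, -1.83 ± 0.14 for BBX15, -1.80 ± 0.19 for OFP16 and -1.77 ± 0.22 for COL2. In all, 3398 features were higher and 2264 lower, 1330 and 194 by at least 2-fold (3011 and 4446 with the processed signals). All 36 rapid stress transcription factors rose, adjusted over the list alone too (median 3.04, camera adjusted p = 4.95e-46, and adjusted p = 0.00297 with an estimated correlation). JAZ repressors (10 rose and 0 fell of 12; 10 and 0 adjusted over the list alone) gave median 2.27, camera adjusted p = 6.49e-14, and adjusted p = 0.00947 with an estimated correlation. CAF1a rose by 3.78 ± 0.32, and CAF1b gave 0.35 ± 0.24, which did not pass (adjusted p = 0.324). Within slide 3, which held 1 unwounded array and 3 arrays at 30 min, 3458 features changed, with slide as a block 3456. The rapid transcription factors had a median of 3.14 there, the senescence list turned from 0.64 to -0.07, and aliphatic glucosinolates lost their call (-0.09, adjusted p = 0.175).

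In caf1b at 90 min the largest rises were 7.33 ± 0.68 for CYP94B1, 6.84 ± 0.37 for CYP94B3, 6.52 ± 0.34 for CYP94C1, 6.45 ± 0.68 for RAP2.6 and 5.90 ± 0.46 for LOX3. The largest falls were -2.77 ± 0.22 for COL2, -2.51 ± 0.26 for EXPA8, -2.39 ± 0.24 for ATSPS4F, -2.22 ± 0.24 for ACD6 and -2.18 ± 0.18 for EXPB1. In all, 4891 features were higher and 3755 lower, 1742 and 476 by at least 2-fold (4382 and 6298 with the processed signals). All 9 jasmonate catabolism genes rose, adjusted over the list alone too (median 4.78, camera adjusted p = 1.61e-11, and adjusted p = 0.0356 with an estimated correlation). Jasmonate biosynthesis (11 rose and 0 fell of 14; 12 and 0 adjusted over the list alone) gave median 3.45, camera adjusted p = 1.03e-08, and adjusted p = 0.0356 with an estimated correlation. Abscisic acid, drought and cold genes (18 rose and 0 fell of 24; 18 and 0 adjusted over the list alone) gave median 2.29, camera adjusted p = 4.74e-12, and adjusted p = 0.0343 with an estimated correlation. CAF1b gave 0.51 ± 0.24, which did not pass (adjusted p = 0.109).

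**Figure D2:**
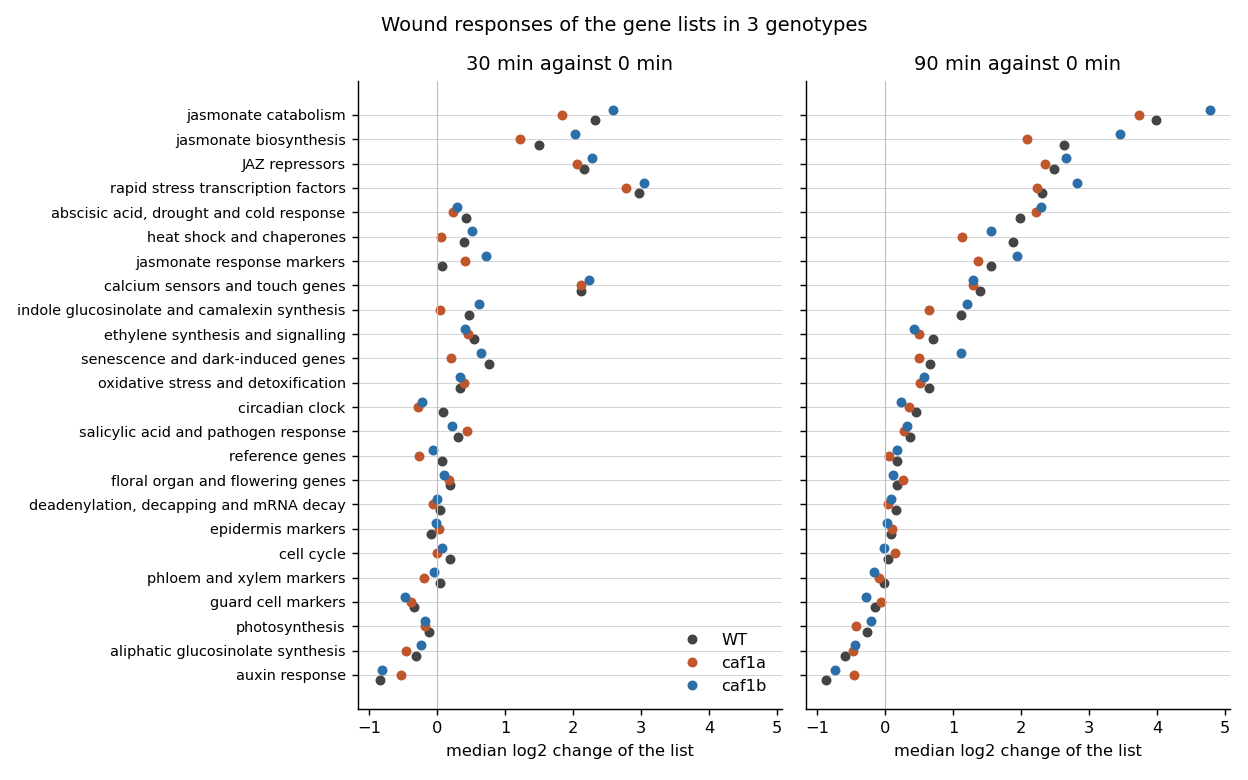
Median log2 change of each of the 24 gene lists (horizontal axis) at 30 min (left) and 90 min (right) against 0 min, with 1 point per genotype; lists are ordered by their WT median at 90 min (vertical axis). Jasmonate catabolism had the largest median at 90 min in each genotype, 3.98 in WT, 3.73 in caf1a and 4.78 in caf1b, and reference genes lay between -0.26 and 0.18 over both times.

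The wound responses of the 3 genotypes, which share no array, overlapped, and the elapsed time is common to all of them. At 30 min 2238 features rose in both WT and caf1a, where independent calls would share 383, and 936 fell in both, against 133, with 2 moving in opposite directions. For WT and caf1b the shared rises numbered 2458 against 401 and the shared falls 1150 against 152, with 1 opposed. At 90 min WT and caf1a shared 3393 rises against 781 and 1707 falls against 311, with 17 opposed. WT and caf1b then shared 3747 rises against 868 and 2427 falls against 508, with 3 opposed. Across features Pearson's r with WT was 0.912 for caf1a and 0.938 for caf1b at 30 min, and 0.924 and 0.946 at 90 min; features are not independent replicates.

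The difference between mutant and WT wound responses was tested directly. At 30 min CAF1a rose less in caf1a by -2.98 ± 0.45 (adjusted p = 0.0188), and CAF1b rose less in caf1b by -3.95 ± 0.34 (adjusted p = 9.11e-07); no other feature passed in this fit at that time. The CAF1a call was lost in 6 of the 12 fits that left out 1 array and without the 3 caf1a arrays described below. With slide as a block the caf1b test at 30 min called 9 features, 8 of them higher. At 90 min AT1G44810, named after its values were seen because it was the single call, differed in caf1a by 0.80 ± 0.13 (SE; adjusted p = 0.040), and limma called 0 features in caf1b. Features at an unadjusted p under 0.05 numbered 2173 and 2503 for caf1a at 30 and 90 min and 1054 and 1155 for caf1b, where chance alone gives 1284.1 of 25682. In the simulation with independent noise, changes of 2-fold were recovered in 74.6% of cases for caf1b at 30 min. Those of 1.41-fold were recovered in 11.9%, so at such noise most small differences would be missed with 3 arrays per group. Jasmonate response markers had a median difference of 0.61 in caf1b at 30 min (camera adjusted p = 0.0157, and adjusted p = 0.843 with an estimated correlation). Heat shock genes had -0.53 in caf1a at 90 min (camera adjusted p = 0.00722, and 0.773 as adjusted p with an estimated correlation); in neither list did a gene pass.

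Against WT, caf1a plants differed by small changes apart from CAF1a and AT4G18930. CAF1a was lower by log2 values of -3.01, -5.99 and -3.43 at 0, 30 and 90 min. AT4G18930, which has no symbol and was chosen after its values were seen, differed by -3.84, -4.30 and -3.90. Also without a symbol and chosen so, AT2G07696 was higher by 0.85, 1.19 and 1.22 at these times. AT2G07695 was higher by 0.92, 0.88 and 0.76, and A_84_P706051 by 1.09, 0.89 and 0.86. The probes of AT2G07696 and AT2G07695 start at 3351392 and 3347760 on chromosome 2, so the differences of these neighbours lie at 1 place. At 0 min AT2G22795 was lower by -1.40 and AT5G10770 by -1.23. The largest changes named next are those among genes with a symbol whose arrays did not overlap between the groups. At 0 min the largest such rises were 1.25 ± 0.24 for GRP2, 0.97 ± 0.21 for THI2.2, 0.85 ± 0.19 for MYB15, 0.84 ± 0.19 for SRO5 and 0.75 ± 0.17 for GH9B13. THI2.2 is a thionin. The largest falls after CAF1a were -0.91 ± 0.17 for MRD1, -0.85 ± 0.16 for SGS3, -0.78 ± 0.15 for SAB and -0.70 ± 0.13 for FNR1, SGS3 acting in RNA silencing. The largest rises at 30 min were 0.70 ± 0.12 for TET9, 0.68 ± 0.13 for CLPB2, 0.59 ± 0.11 for KCS17 and 0.45 ± 0.08 for QQT1. Those at 90 min were 1.18 ± 0.21 for THI2.2, 1.09 ± 0.18 for EXLB1, 0.97 ± 0.24 for CAB1, 0.95 ± 0.22 for WRKY22 and 0.90 ± 0.16 for SLP3, EXLB1 being an expansin-like protein and CAB1 a chlorophyll-binding protein. Falls at 90 min were -1.28 ± 0.30 for CIPK9, -1.07 ± 0.17 for MRD1, -0.96 ± 0.22 for NET2D and -0.94 ± 0.20 for TPS03. The largest adjusted p among the genes named here was 0.0471 (limma, n = 3).

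Features higher and lower in caf1a numbered 87 and 44 at 0 min, 24 and 4 at 30 min, and 233 and 41 at 90 min, of which 10, 3 and 9 in all changed by at least 2-fold. These counts depend on single arrays: leaving out 1 array gave 17 to 91 at 0 min, 5 to 703 at 30 min and 7 to 745 at 90 min. Fits of only the 2 groups gave 7, 2 and 7. The balance of directions moved too. The processed signals gave 48 higher and 38 lower at 0 min, 46 and 7 at 30 min, and 140 and 45 at 90 min. Without replicate 2 of caf1a at 90 min, 3 were higher and 4 lower at that time. No gene list held its camera call with an estimated correlation in these 3 tests. Aliphatic glucosinolate synthesis had a median of -0.24 at 30 min (camera adjusted p = 0.00839, adjusted p = 0.62 with an estimated correlation). Heat shock genes had -0.41 at 90 min (camera adjusted p = 0.0193, adjusted p = 0.764 with an estimated correlation). The arrays also varied along a trend over many genes, which was not tested over arrays. The level of genes of families with long products less that of families with short products had, in caf1a, means of -0.08 ± 0.24, -0.28 ± 0.30 and -0.09 ± 0.13 (SD, n = 3) at 0, 30 and 90 min. In WT the means were 0.13 ± 0.08, 0.02 ± 0.03 and 0.12 ± 0.06, and in caf1b 0.17 ± 0.07, -0.11 ± 0.18 and -0.07 ± 0.09. Single arrays carry the caf1a means: at 0 min replicate 3 lay at -0.36 and the others at 0.05 and 0.05, and at 30 min replicate 3 lay at -0.62 and the others at -0.10 and -0.11. With this index as a covariate the counts were 155, 3 and 52. Without the 3 caf1a arrays farthest along principal component 3 they were 32, 5 and 39. Both were chosen after the data were seen. With the covariate the median size of the called changes went only from 0.61 to 0.57, 0.69 to 0.61 and 0.57 to 0.49 at the 3 times. At 0 min, with slide as a block, 6 features changed, SRO5 turned to -0.02 and the rapid stress transcription factors turned from 0.18 to -0.57. Salicylic acid genes then had a median of -1.43 (adjusted p = 3.44e-13) and jasmonate catabolism 1.41 (0.000999), and calls were also gained for the heat shock, abscisic acid, calcium, jasmonate biosynthesis, and phloem and xylem lists. That fit rests on a single link, since the only slide with both genotypes held the 3 caf1a arrays at 0 min and 1 WT array at 90 min.

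**Figure D3:**
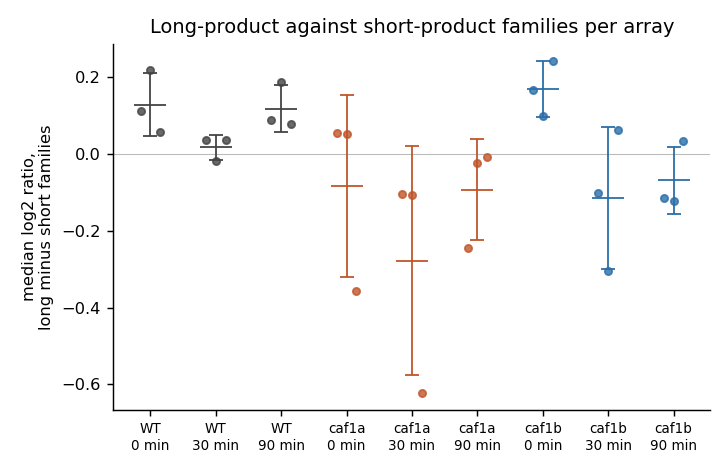
Median log2 ratio of 342 genes of long-product families minus that of 444 genes of short-product families (vertical axis) on each array, by genotype and time (horizontal axis); points are arrays, the bar is the mean and the whiskers are the SD of 3 arrays. The lowest array, replicate 3 of caf1a at 30 min, lay at -0.62, and the WT arrays lay between -0.02 and 0.22.

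Against WT, caf1b plants differed at 8, 5 and 5 features at 0, 30 and 90 min, with large changes at MRD1, AT5G24240 and CAF1b. Leaving out 1 array gave 5 to 19, 4 to 6 and 4 to 8, the scanner's processed signals gave 19, 6 and 10, and fits of only the 2 groups gave 3, 4 and 3. MRD1 was lower by log2 values of -4.17 ± 0.17, -4.74 ± 0.17 and -3.85 ± 0.17 at 0, 30 and 90 min, and CAF1b by -4.56 ± 0.24 and -2.61 ± 0.24 at 30 and 90 min. AT5G24240 was higher by 3.92, 4.06 and 4.31. Its ratio hardly varied between WT arrays, with SDs of 0.011, 0.005 and 0.055 at the 3 times. A signal at background can give such values, so these differences may be lower bounds. HEI10 differed by -0.74 ± 0.13 at 90 min (limma adjusted p = 0.0364, well above background on 2 of the 3 caf1b arrays). Its probe starts at 19970145 on chromosome 1, near that of MRD1 at 19967163. The probe A_84_P706643, named below, starts between them at 19967423, so these 3 differences lie at 1 place. In all 3 features were higher and 5 lower at 0 min, 1 and 4 at 30 min, and 1 and 4 at 90 min. The others were probes without a locus and small changes: A_84_P735866 differed by -0.99, -0.85 and -1.11 at the 3 times, A_84_P703485 by -1.59 and -1.32 at 0 and 30 min. At 0 min alone A_84_P706051 differed by 0.91, A_84_P706643 by -0.76, AT5G03090 by -0.77 and AT5G24620 by 0.58. Those without a symbol were named after their values were seen. Several of these features set caf1a apart from WT in the same direction. Both mutants were compared with the same WT arrays, so a deviation of those arrays would shift both mutants alike. A_84_P706051 was higher in caf1a by 1.09, 0.89 and 0.86 at the 3 times. At 0 min the means in WT, caf1a and caf1b were 0.55, -0.14 and -0.44 for A_84_P735866. They were 0.71, -0.47 and -0.88 for A_84_P703485. At 0 min AT5G24240 lay near WT in caf1a (-2.96 in WT, -2.86 in caf1a). In unwounded caf1b the jasmonate lists had medians of -0.33 for biosynthesis, -0.23 for JAZ repressors, -0.60 for catabolism and -0.48 for response markers, without any gene passing (camera adjusted p = 0.00932, 0.00932, 0.00499 and 0.000609). None of these calls held with an estimated correlation (adjusted p = 0.449 for each). WT and caf1b share no slide, so slide and genotype cannot be told apart in these tests except through caf1a.

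**Figure D4:**
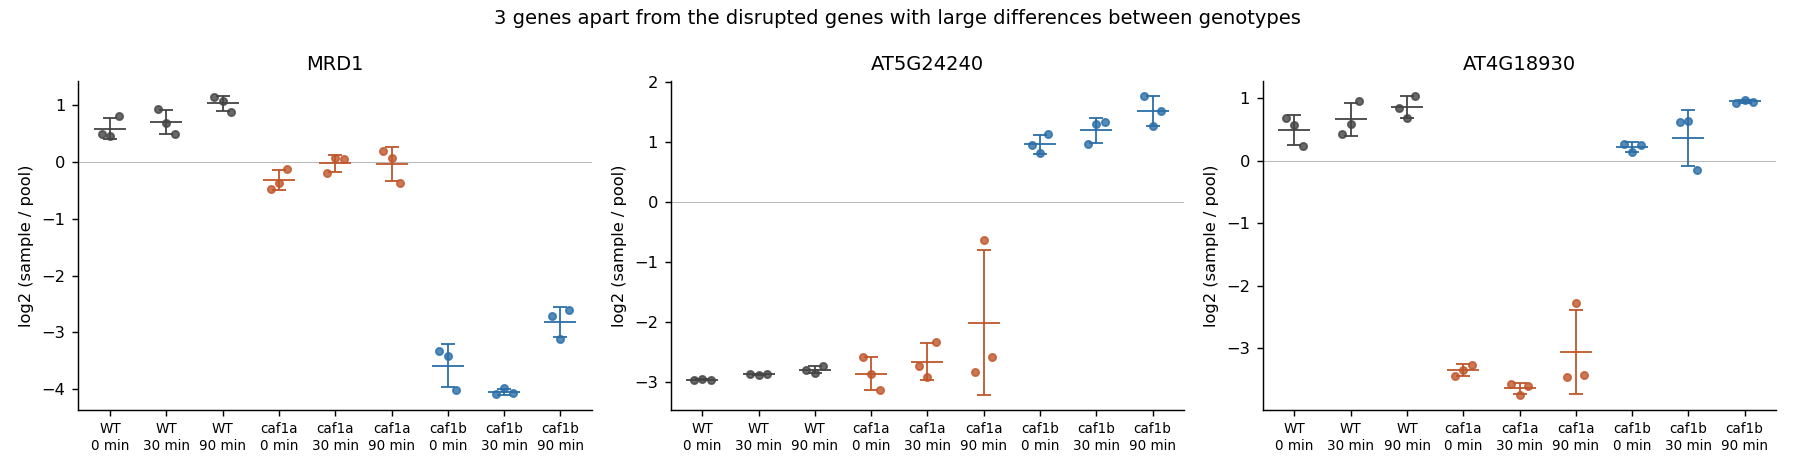
Log2 ratio of sample over pooled reference (vertical axis) for MRD1, AT5G24240 and AT4G18930 on each of the 27 arrays, by genotype and time (horizontal axis); points are arrays, the bar is the mean and the whiskers are the SD of 3 arrays. MRD1 was low and AT5G24240 high on all 9 caf1b arrays, and AT4G18930 was low on all 9 caf1a arrays.

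Compared directly and averaged over the 3 times, caf1b and caf1a differed most at the 2 disrupted genes, MRD1 and, among loci without a symbol, AT4G18930 at 3.86 and AT5G24240 at 3.73. Higher in caf1b were, among others, 4.36 ± 0.18 for CAF1a, 1.28 ± 0.11 for QQS, 0.43 ± 0.09 for GI, 0.42 ± 0.07 for MKP1 and 0.31 ± 0.07 for VHA-A3, QQS being a regulator of starch content and GI a clock gene. Lower in caf1b were -3.35 ± 0.10 for MRD1, -2.79 ± 0.14 for CAF1b, -0.91 ± 0.11 for FLC, -0.83 ± 0.13 for GSTF12 and -0.82 ± 0.10 for EXLB1, FLC being a repressor of flowering and GSTF12 a glutathione transferase of anthocyanin transport. The largest adjusted p among these 10 genes was 0.0309 (limma, 9 arrays per genotype). In all, 82 features were higher and 428 lower in caf1b, 5 and 2 by at least 2-fold. The processed signals gave 269 and 654, and leaving out 1 array gave totals of 181 to 1273. Of 20 clock genes 2 passed, both higher in caf1b, and of 36 rapid stress transcription factors 2 passed, both lower; the second list gave median -0.14, camera adjusted p = 0.014, and adjusted p = 0.825 with an estimated correlation. With the long and short family index as a covariate 119 features differed, and without the 3 caf1a arrays 74. With the covariate the median size of the 510 called changes went from 0.319 to 0.255, and 100% kept their sign.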

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

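The regroupings of arrays cited here were chosen only after the results were seen. CAF1a, the gene disrupted in caf1a, rose less after 30 min of wounding in caf1a than in WT by a log2 difference of -2.98 ± 0.45 (SE, n = 3 per group; limma adjusted p = 0.019). This call was lost in 6 of the 12 fits that left out 1 array (WT at 0 min replicate 3, WT at 30 min replicates 2 and 3, caf1a at 0 min replicates 2 and 3, caf1a at 30 min replicate 1) and without the 3 caf1a arrays. Its log2 ratio went from -2.02 to 1.77 in WT and from -5.03 to -4.22 in caf1a. CAF1b, disrupted in caf1b, rose less after 30 min in caf1b by -3.95 ± 0.34 (limma adjusted p = 9.1e-07), going from -2.95 to 1.36 in WT and from -3.56 to -3.21 in caf1b. In each mutant the disrupted gene also lay below WT at 30 min, by -5.99 for CAF1a and -4.56 for CAF1b, while CAF1b at 0 min did not pass (-0.61).

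AT1G44810 differed in the 90 min wound response of caf1a by 0.80 ± 0.13 (SE, n = 3 per group; limma adjusted p = 0.040). It went from 0.16 to -0.35 in WT and from -0.34 to -0.04 in caf1a. The call was lost in 9 of the 12 fits that left out 1 array, with the processed signals, the deposited table, replicate number as a block and only the groups compared, and without the 3 caf1a arrays.

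By the count of calls alone, the single call for caf1a at 30 min could be due to chance. Each regrouping counted calls of any feature, whichever gene it was. Of 100 regroupings, the real one included, 22 gave as many features as the real 1 for caf1a at 30 min, 9 as many as 1 for caf1a at 90 min and 13 as many as 1 for caf1b at 30 min. For caf1b at 90 min limma called 0 (1155 at an unadjusted p under 0.05), so all 100 reach that count whatever the data and nothing is tested. The highest counts in other regroupings were 91, 13, 12 and 42. Moving arrays between genotypes at 1 time also carries the genotype difference into these tests. With that difference removed, 13 regroupings gave as many for caf1a at 30 min, and 3 each for caf1a at 90 min and caf1b at 30 min. For these last 2 tests the forms disagree, so chance stays open for their counts as well. The calls at 30 min were CAF1a and CAF1b, genes fixed by the genotypes. On WT arrays CAF1a lay at -2.22 to -1.80 at 0 min and 1.49 to 2.13 at 30 min. On caf1a arrays it lay at -5.23 to -4.71 and -4.30 to -4.10. CAF1b lay at -3.16 to -2.64 and 0.66 to 2.13 in WT. In caf1b it lay at -3.83 to -3.37 and -3.30 to -3.14. These values argue against chance for the 2 genes.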

How the results depend on the processing

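These alternatives were chosen before the data were examined, except the covariate, the filter on Cy5 and the removal of 3 caf1a arrays, which were chosen only after the results were seen. Where a count changed, the cause was not tested. Counts of features changed are given beside those of the first fit. The quantile alternative could not change a ratio, and the filters on dim features and the mean over probes left the counts of every comparison within the bounds set for a change. Agilent's processed signals gave 86 for caf1a against WT at 0 min (131 at first), 53 at 30 min (28), 19 and 10 for caf1b against WT at 0 and 90 min (8 and 5). It also gave 2 for the caf1a difference in wound response at 30 min (1), 2 for that of caf1b at 90 min (0) and 923 for caf1b against caf1a (510). The deposited value table gave 70, 52, 19, 11 and 2 for the first 5 of these, 3 for the caf1b difference in wound response at 30 min (1). It gave 4 at 90 min and 910 for caf1b against caf1a. Slide as a random block gave 254 for caf1a against WT at 0 min, 2 for the caf1a difference at 90 min (1) and 124 for caf1b against WT averaged over time (65). Slide as a fixed block gave 3947 for WT at 90 min (8034), 3456 for caf1b at 30 min (5662). It gave 6 for caf1a against WT at 0 min and 9 for the caf1b difference at 30 min; within slide 3 the caf1b count at 30 min was 3458. With either of these last 2 the senescence list of caf1b at 30 min turned to -0.071, and with the fixed block SRO5 turned to -0.023 and the rapid stress transcription factors to -0.571 in caf1a against WT at 0 min.

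Replicate number as a block gave 180 for caf1a against WT at 90 min (274) and 0 for the caf1a difference at 90 min. Fits of only the groups compared gave 2650 for caf1a at 30 min (5233), 7, 2 and 7 for caf1a against WT at the 3 times. They gave 3 and 3 for caf1b against WT at 0 and 90 min and 0 for the caf1a difference at 90 min. Without the 3 caf1a arrays the counts were 32, 5 and 39 for caf1a against WT at the 3 times, 0 and 0 for its differences in wound response. They were 74 for caf1b against caf1a, 1679 for caf1a against WT averaged (5289) and 231 for caf1b against WT averaged. With the covariate they were 3 and 52 for caf1a against WT at 30 and 90 min, 19 for the caf1a difference at 90 min, 119 for caf1b against caf1a, and 255 and 109 for caf1a and caf1b against WT averaged. P5CS1, LNK1 and EIN3 turned to 0.004, 0.023 and 0.006 in caf1a against WT averaged. Camera calls were fewer with an estimated correlation, which weakened 95 of them.

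Leaving out each array in turn gave 3852 to 4200 for WT at 30 min, 6779 to 7558 for WT at 90 min and 3778 to 5762 for caf1a at 30 min. It gave 5225 to 6345 for caf1a at 90 min, 4073 to 5324 for caf1b at 30 min and 6768 to 8187 for caf1b at 90 min. Against WT it gave 17 to 91, 5 to 703 and 7 to 745 for caf1a and 5 to 19, 4 to 6 and 4 to 8 for caf1b at the 3 times. The differences in wound response had 0 to 4 and 0 to 5 for caf1a and 1 to 3 and 0 to 3 for caf1b at 30 and 90 min. Ranges were 181 to 1273 for caf1b against caf1a, 3514 to 4398 for WT at 90 against 30 min, and 3628 to 6385 and 21 to 154 for caf1a and caf1b against WT averaged.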

Other observations

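The tests in this part were chosen only after the patterns they address were seen; what each explanation predicts was written before the outcome was known for the covariate, the slide block and the caf1a position test, and after it for the others. In WT the times 30 and 90 min after wounding were also compared with each other. Rising from 30 to 90 min were 4.56 ± 0.48 for RNS1, 3.92 ± 0.40 for PRN, 3.91 ± 0.47 for UGT76E12, 3.91 ± 0.68 for RAP2.6 and 3.87 ± 0.66 for BSMT1, RNS1 being a wound-induced ribonuclease and BSMT1 a methyltransferase that forms methyl salicylate. Falling were -3.05 ± 0.29 for SZF1, -2.95 ± 0.29 for TDR1, -2.78 ± 0.41 for NAC090, -2.75 ± 0.33 for DIC2 and -2.72 ± 0.22 for RRTF1, with SZF1 a zinc finger protein of salt stress and RRTF1 a redox-responsive transcription factor. CAF1a fell by 2.34. In all, 2324 features were higher and 2301 lower at 90 than at 30 min (limma adjusted p, n = 3 per group), 632 and 427 by at least 2-fold.

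Of the gene lists with camera calls between these times, none held with an estimated correlation. The abscisic acid, drought and cold list had a median of 1.70 (camera adjusted p = 1.53e-14; adjusted p = 0.0583 with an estimated correlation), with 17 genes higher and 0 lower (adjusted over the list alone 17 and 0). Heat shock and chaperone genes had 1.21 (camera adjusted p = 2.49e-09; adjusted p = 0.126 with an estimated correlation), 15 higher and 1 lower. The rapid stress transcription factors had -1.06 (camera adjusted p = 2.46e-09; adjusted p = 0.198 with an estimated correlation), 3 higher and 23 lower. Calcium and touch genes had -1.07 (camera adjusted p = 1.19e-05; adjusted p = 0.21 with an estimated correlation), 1 higher and 12 lower. Within slide 6, which held both times, the first 3 of these medians were 2.06, 1.52 and -1.45. Aliphatic glucosinolate and senescence calls were lost there (adjusted p = 0.214 and 0.0822), and calls were gained for salicylic acid (median -0.43) and mRNA decay (0.02).

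Averaged over the 3 times, caf1a differed from WT at 2794 features higher and 2495 lower, of which 1 and 6 by at least 2-fold. CAF1a differed by -4.14 ± 0.18, and rises included 0.88 ± 0.14 for CAB1, 0.78 ± 0.10 for EXLB1, 0.74 ± 0.13 for AGP41 and 0.72 ± 0.12 for WRKY22. Falls included -1.04 ± 0.17 for NPX1, -1.03 ± 0.20 for NET4B, -0.97 ± 0.19 for CLPC1 and -0.95 ± 0.17 for MFP1 (limma, 9 arrays per genotype). Genes of long-product families lay lower than those of short-product families by -0.220 between caf1a and WT, at medians of -0.143 over 342 and 0.0775 over 444 genes. Random sets of these sizes gave -0.0301 to 0.0309 in 95% of 10000 draws, across genes; genes are not independent replicates. The same difference was -0.101 for caf1b averaged over time, from 0.0453 at 0 min to -0.143 and -0.213 at 30 and 90 min. The trend was thus seen in caf1b too at the wounded times. Both mutants were compared with the same WT arrays, so these differences are not independent. A bias of RNA or labelling with transcript length is consistent with these values, and they leave an effect of the mutants on long transcripts open. With the index of each array as a covariate the count was 255 in place of 5289; the median size of the called changes went from 0.31 to 0.15 and their median SE only from 0.0830 to 0.0819, so the array trend may account for most of the calls, although the index differs with genotype and can take a genotype effect with it. The index also varied widely between replicates of a group. Its lowest caf1a values were -0.36 at 0 min (replicate 3), -0.62 at 30 min (replicate 3) and -0.25 at 90 min (replicate 1). These are the 3 caf1a arrays removed for principal component 3, so the covariate and that removal are not separate checks. Slide stays open: as a random block it had a correlation near 0 and left 5913 features, which tests nothing.

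The caf1b plants differed from WT in 65 features averaged over the 3 times, 43 higher and 22 lower, by a few large changes. Leaving out 1 array gave 21 to 154. The processed signals gave 36 higher and 37 lower, of which 34 were called in the first fit too, so the balance depends on the scaling. AT5G24240 was higher by 4.09, which may be a lower bound as above. MRD1 was lower by -4.25 ± 0.10 and CAF1b lower by -2.59 ± 0.14, while QQS was higher by 0.99 ± 0.11 and GRP2 by 0.71 ± 0.14. Averaged in the same way and against the same WT arrays, caf1a also had GRP2 higher by 0.82 and MRD1 lower by -0.90. QQS was not higher in caf1a, at -0.72 against -0.38 in WT at 0 min. Against a slide effect, MRD1 and AT5G24240 differed between caf1b and caf1a by -3.21 and 2.48 (the smaller size, tested as 2.478) on slide 2, which held caf1b at 0 min and caf1a at 90 min, n = 2 each. The largest gap between replicates there was 0.438 for MRD1 and 1.95 for AT5G24240, the latter from caf1a replicate 2, described below, at -0.63. In WT MRD1 went only from 0.58 to 1.03 and AT5G24240 from -2.96 to -2.79 between these times. The WT signal of AT5G24240 may lie at background, where a change with time might not show. Of the 64 called features other than CAF1b, 6 had probes within 2 Mb of the CAF1b probe, AT5G24240 at 866 kb among them (10000 random sets: median 2, one-sided permutation p = 0.039). The test was set after the place of AT5G24240 was seen. Without this gene 5 remained, as many as the 95% value of the random sets (permutation p = 0.09). Among these is AT5G24250 at 868 kb, beside AT5G24240, so the place that prompted the test is still counted. The random sets also treat neighbouring features as independent. Position near CAF1b stays open, and MRD1, on chromosome 1, does not lie there. For caf1a, AT4G18930 differed by -4.01, and it lies on chromosome 4, while CAF1a lies on chromosome 3. Of the 64 features with the smallest p, 1 lay within 2 Mb of the CAF1a probe, A_84_P721499 (random median 1, 95% value 3, permutation p = 0.71). Position near CAF1a thus likely does not account for most of that set. With so few features awaited by chance, a single linked place could be missed, and the set may follow the array trend above.

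One array stood apart from the other caf1a arrays, replicate 2 at 90 min on slide 2. AT5G24240 was -0.63 on it and -3.13 to -2.33 on the other caf1a arrays, and AT4G18930 was -2.28 against -3.74 to -3.26. CAF1a was -3.30 against -5.23 to -4.10, and QQS was -0.15 against -1.18 to -0.54. All of these values lay toward those of the caf1b arrays, and for AT5G24240 only caf1b arrays lay higher. MRD1, which is low in caf1b, lay within the other caf1a arrays (0.06 against -0.47 to 0.20). No test was made of the cause. Without this array caf1a and WT differed at 7 features at 90 min in place of 274, but other single arrays had a like effect: 12 without caf1a replicate 1, 32 without WT replicate 1 and 41 without WT replicate 2. The 90 min response of caf1a had 6125 in place of 6696 without it.

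Regroupings of the compared arrays gave the following counts. For the comparisons of 2 groups the 10 possible splits are too few for a share under 0.05. The real count and the highest of the others were 4753 and 4 for WT at 30 min, 8034 and 1 for WT at 90 min, and 5233 and 123 for caf1a at 30 min. They were 6696 and 0 for caf1a at 90 min, 5662 and 0 for caf1b at 30 min, 8646 and 0 for caf1b at 90 min, and 4625 and 1 for WT at 90 against 30 min. Between caf1a and WT they were 131 and 0 at 0 min and 274 and 0 at 90 min, and between caf1b and WT 8 and 2, 5 and 0, and 5 and 2 at the 3 times. In each of these 1 split, the real one, gave as many. Between caf1a and WT at 30 min 3 of the 10 splits gave as many as the real 28, the highest 195, which joined WT replicate 3 with caf1a replicates 2 and 3. For the tests averaged over time, 1 of 100 regroupings, the real one, reached each count. The counts were 510 for caf1b against caf1a (highest other 2), 5289 for caf1a against WT (highest other 142) and 65 for caf1b against WT (highest other 1). A random grouping of these arrays is thus unlikely to give such counts. Slide largely goes with genotype and the regroupings break up both, so they do not separate the 2.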
